A study of Homo sapiens with 15 samples.

How the data were processed

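RNA was sequenced from MCF7 cells treated for 6 days with DMSO, or with tamoxifen, fulvestrant, H3B-6545 or H3B-9709 at 100 nM, with medium and compounds renewed on day 3, and the libraries were stranded, per the labels' protocols. The 15 libraries formed 5 groups of 3. The labels give each library a sequencing lane: lane 7 held the DMSO libraries and tamoxifen replicate 1, lane 6 tamoxifen replicates 2 and 3 and fulvestrant replicates 1 and 2, lane 4 fulvestrant replicate 3, lane 3 all H3B-6545 libraries and H3B-9709 replicates 1 and 2, and lane 2 H3B-9709 replicate 3.

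The deposited estimated count of each gene and the TPM values came from kallisto, per the submitters' processing notes, which also name genome build hg19. The kallisto version, the transcript annotation and how transcripts were summed to genes were not given in the sources used here. Genes were taken by the symbols in the tables, which hold no coordinates, so none are given. Of the count values, 54.0% were not whole, and all were rounded to whole numbers before testing. Totals per library ran from 29.96 to 64.9 megacounts. kallisto divides reads among similar transcripts, so levels of genes with near-identical copies are uncertain.

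From these tables, edgeR (4.0.16, in R 4.3.3) kept 21875 of 34484 genes with filterByExpr over the 5 groups and left out 12609. Counts were scaled by TMM, 1 model was fitted to all 15 libraries with group as the only term (robust quasi-likelihood fit; common biological coefficient of variation 4.57%), and 8 comparisons were tested. A gene was called, and said to rise, fall, be higher or be lower, at a Benjamini-Hochberg adjusted p below 0.05; changes of at least 2-fold (a log2 fold change of 1) were counted too. The standard error is the size of the log2 fold change divided by the root of its F statistic, and intervals at 95% use the fit's total degrees of freedom. The p-values measure only the spread between libraries, and the labels do not say that a replicate number marks a shared culture.

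Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, for lists with at least 5 measured members, with adjustment over the lists of a comparison. The 29 lists were estrogen-induced genes, estrogen-repressed genes, replication and G1/S genes, mitosis and G2/M genes, CDK inhibitors and pocket proteins, cholesterol synthesis genes, fatty acid synthesis genes, interferon-stimulated genes, MHC class I and antigen processing genes, unfolded protein response genes, ATF4 and amino acid response genes, NRF2 target genes, aryl hydrocarbon receptor target genes, p53 target genes, BCL2 family genes, receptor tyrosine kinase signalling genes, nuclear receptors and coregulators, luminal epithelial genes, basal epithelial genes, mesenchymal genes, MYC and ribosome biogenesis genes, NF-kB target genes, hypoxia and glycolysis genes, lysosome and autophagy genes, oxidative phosphorylation nuclear genes, mitochondrially encoded genes, fibroblast markers, leukocyte markers and endothelial markers. TIGAR and PECAM1 were not in the tables, and other members were matched by older symbols where needed (WISP2 for CCN5, SLC9A3R1 for NHERF1, IL8 for CXCL8). With an estimated correlation in place of the preset one, 63 list calls were lost, and for 53 of them this gave the highest adjusted p of all alternatives. In 17 of 232 list tests the median, the mean and the test differed in sign, and 0 of these were called by camera. The fry test (limma) asked whether a list's genes changed in either direction, without setting them against other genes.

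The lists, tests, naming rule and most alternatives were fixed before the data were examined. Named genes are a panel (ESR1, PGR, GREB1, TFF1, PDZK1, CXCL12, MYC, CCND1, MKI67, CCNE2, ERBB2, HMGCS1), the 6 highest and 6 lowest log2 fold changes against DMSO and the 3 highest and 3 lowest between compounds, and, for each called list described, the 2 called members with the lowest p. The extremes were taken among called genes with a mean CPM of at least 5 and no overlap of libraries, leaving out clone and locus names (also names of the KIAA, LINC, FLJ and open reading frame kind). List members serve as examples, and any other gene is said to have been chosen after its values were seen.

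The alternatives were RLE size factors, library size alone, DESeq2 (1.42.0), no filter on low counts, a mean CPM of at least 5, a replicate block, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a TPM of at least 1 in 3 libraries, limma on unfiltered TPM, lane as a term, fits on only the 6 libraries compared, on 1 lane, and without each library in turn. Lane could not be a term between an H3B compound and the other groups, which shared no lane. For the comparisons with DMSO, unchanged groups were simulated with shared controls.

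Simulated test data had 50 genes changed at each fold among 21875. At 1.25, 1.5, 2 and 4-fold, edgeR recovered 18, 28, 43 and 44 for tamoxifen against DMSO (12 false among 145 calls) and 21, 27, 42 and 47 for H3B-6545 against H3B-9709 (2 false among 139 calls). In both, camera called the raised list and 0 of 21 unchanged ones with either correlation, which favours neither.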

Results

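RNA levels were measured in MCF7, an established human breast cancer cell line that grows in response to estrogen, after 6 days with DMSO (the solvent control) or with tamoxifen, fulvestrant, H3B-6545 or H3B-9709, each at 100 nM. Every group had 3 libraries, and the labels do not say whether these came from separate cultures. The total estimated count was 64.9, 44.5 and 59.8 megacounts in the DMSO libraries, 42.6, 29.96 and 34.4 with tamoxifen, 37.6, 34.9 and 45.9 with fulvestrant, 50.7, 38.9 and 51.1 with H3B-6545 and 45.2, 47.9 and 47.4 with H3B-9709. Of 34484 genes in the count table, 21875 had counts high enough to be tested. The first principal component held 48.1% of the variance and set the DMSO libraries (-92.8 to -88.2) apart from all libraries with a compound (7.69 to 10.1 with tamoxifen up to 41.6 to 43.7 with fulvestrant). The second held 17.7% and set fulvestrant (48.0 to 51.9) apart from tamoxifen (-25.4 to -23.8). Genes encoded in mitochondrial DNA took 5.49 ± 0.0628% of the counts (mean ± SD, n = 3) with DMSO, 4.35 ± 0.0429% with tamoxifen, 4.39 ± 0.182% with fulvestrant, 4.23 ± 0.178% with H3B-6545 and 4.19 ± 0.0505% with H3B-9709. Levels below are means ± SD of TPM over 3 libraries, and each log2 fold change is given ± SE from edgeR's quasi-likelihood test.

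The comparison of tamoxifen, a selective estrogen receptor modulator, with DMSO asked which RNA levels the drug changed. TFF1, a trefoil peptide, fell from 1891 ± 57.3 to 25.8 ± 1.03 TPM, a log2 fold change of -6.30 ± 0.068, and GREB1, a cofactor of the estrogen receptor, fell from 345 ± 11.6 to 9.79 ± 0.427 TPM, a log2 fold change of -5.23 ± 0.053. The progesterone receptor gene PGR (log2 fold change -3.35 ± 0.056), the chemokine gene CXCL12 (-3.78 ± 0.081) and the scaffold gene PDZK1 (-1.48 ± 0.072) fell too. CCND1 (log2 fold change -1.90 ± 0.043), which encodes cyclin D, CCNE2 (-1.64 ± 0.101), a cyclin E gene, and MKI67 (-2.86 ± 0.055), the proliferation marker, fell with them. The receptor gene ESR1 (log2 fold change -0.66 ± 0.035) fell less, while ERBB2 (0.66 ± 0.052), a receptor tyrosine kinase gene, and MYC (0.30 ± 0.041) rose. All these panel genes were called at an edgeR adjusted p of 4.37e-07 or less. HMGCS1, an enzyme of early cholesterol synthesis, had a log2 fold change of 0.02 ± 0.062 and was not called (edgeR adjusted p = 0.789).

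Further genes at the low end were TFF3 (log2 fold change -5.08 ± 0.105), another trefoil peptide, CASP14 (-4.69 ± 0.119), a caspase of skin cells, NPY1R (-4.37 ± 0.062), a neuropeptide Y receptor, and ELOVL2 (-4.03 ± 0.053), which lengthens polyunsaturated fatty acids. At the high end stood MPPED1 (log2 fold change 4.99 ± 0.119), ADCY5 (4.78 ± 0.110), an adenylyl cyclase, NT5E (4.76 ± 0.097), a surface enzyme that makes adenosine, ACHE (4.63 ± 0.099), acetylcholinesterase, KRT13 (4.58 ± 0.088), a keratin, and IGHG4 (4.37 ± 0.146), an immunoglobulin heavy chain gene whose level is uncertain because its reads overlap those of close copies. The edgeR adjusted p of these 10 genes was at most 6.7e-20. edgeR called 11805 of the 21875 genes, 5824 higher and 5981 lower, and 1481 rose and 1112 fell at least 2-fold. On log2(TPM + 1) the higher share of the calls was 61.7% in place of 49.3%.

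For tamoxifen, camera called 18 of the 29 lists, 10 higher and 8 lower, and 11 held with an estimated correlation. Mitosis and G2/M genes were lower on balance (median log2 fold change -2.75, camera adjusted p = 2.53e-29): of 40 members, all 40 fell, with 40 called adjusted over the list alone. Examples were MKI67 (log2 fold change -2.86 ± 0.055) and PRC1 (-2.68 ± 0.046), which bundles spindle microtubules. Among 42 replication and G1/S genes, 40 fell and 2 were not called, with 40 called adjusted over the list alone (median log2 fold change -1.76, camera adjusted p = 2.97e-25). Among them, RRM2 (log2 fold change -2.97 ± 0.063), a subunit of ribonucleotide reductase, and UHRF1 (-2.81 ± 0.070), which maintains DNA methylation, had the lowest p-values. Camera placed the estrogen-induced genes lower than other genes (median log2 fold change -0.73, camera adjusted p = 1.66e-06), and of 44 members 10 rose, 29 fell and 5 were not called, with 39 called adjusted over the list alone. Members that rose included KRT13 (log2 fold change 4.58 ± 0.088), AGR3 (1.94 ± 0.073), a protein disulfide isomerase relative, SERPINA1 (1.27 ± 0.056), a protease inhibitor, and RET (0.97 ± 0.054), a receptor tyrosine kinase. Of the 26 estrogen-repressed genes, 21 rose, 3 fell and 2 were not called (median log2 fold change 0.62, camera adjusted p = 1.92e-07), and 25 were called adjusted over the list alone. Of these, BCAS1 (log2 fold change 2.40 ± 0.042) and TGFB2 (4.23 ± 0.073), a growth factor of the TGF-beta family, rose. Hypoxia and glycolysis genes were lower on balance (median log2 fold change -0.96, camera adjusted p = 1.36e-05): of 20 members, 3 rose, 15 fell and 2 were not called, with 18 called adjusted over the list alone. Here LDHA (log2 fold change -2.45 ± 0.042), lactate dehydrogenase, and BNIP3 (-2.13 ± 0.045), a mitophagy receptor, fell.

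Among 25 cholesterol synthesis genes, 17 fell and 8 were not called, with 17 called adjusted over the list alone (median log2 fold change -0.38, camera adjusted p = 1.86e-05). FDFT1 (log2 fold change -1.16 ± 0.048), squalene synthase, and DHCR7 (-0.81 ± 0.047), which completes cholesterol synthesis, were called lower. Camera placed the NF-kB target genes higher than other genes (median log2 fold change 1.13, 0.46 on unfiltered TPM, camera adjusted p = 1.25e-06), and of 16 members 14 rose and 2 were not called, with 14 called adjusted over the list alone. RELB (log2 fold change 2.39 ± 0.122), a subunit of NF-kB, and NFKBIA (0.83 ± 0.041), its inhibitor, rose. Of the 24 NRF2 target genes, 18 rose, 3 fell and 3 were not called (median log2 fold change 0.60, camera adjusted p = 6.4e-06), and 22 were called adjusted over the list alone. AKR1C2 (log2 fold change 3.04 ± 0.070), an aldo-keto reductase with close copies that make its count uncertain, and SLC7A11 (3.09 ± 0.070), the cystine transporter, rose. Lysosome and autophagy genes were higher on balance (median log2 fold change 0.35, camera adjusted p = 4.49e-06): of 27 members, 19 rose, 3 fell and 5 were not called, with 24 called adjusted over the list alone. They included PSAP (log2 fold change 1.10 ± 0.039), a sphingolipid activator precursor, and SQSTM1 (1.03 ± 0.038), an autophagy receptor. Among 19 basal epithelial genes, 11 rose, 3 fell and 5 were not called, with 14 called adjusted over the list alone (median log2 fold change 0.90, 0.39 on unfiltered TPM, camera adjusted p = 0.00123). KRT81 (log2 fold change 3.58 ± 0.09999), a keratin with close copies, and KRT15 (2.17 ± 0.062) led them.

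Camera placed the interferon-stimulated genes higher than other genes (median log2 fold change 1.13, 0.64 on unfiltered TPM, camera adjusted p = 1.25e-06, adjusted p = 0.301 with an estimated correlation), and of 35 members 24 rose, 3 fell and 8 were not called, with 28 called adjusted over the list alone. ISG20 (log2 fold change 1.40 ± 0.104), an exonuclease, and IRF7 (1.28 ± 0.086), a transcription factor of the interferon response, rose. Of the 14 MHC class I and antigen processing genes, 10 rose, 1 fell and 3 were not called (median log2 fold change 0.66, camera adjusted p = 0.00638, adjusted p = 0.345 with an estimated correlation), and 12 were called adjusted over the list alone. Examples were ERAP1 (log2 fold change 0.73 ± 0.064), which trims peptides, and TAP1 (1.05 ± 0.084), which transports them. ATF4 and amino acid response genes were higher on balance (median log2 fold change 0.37, 0.10 on unfiltered TPM, camera adjusted p = 0.025, adjusted p = 0.163 with an estimated correlation): of 21 members, 10 rose, 6 fell and 5 were not called, with 16 called adjusted over the list alone. That call was lost with a mean CPM of at least 5 and only the 6 libraries compared (camera adjusted p from 0.00505 to 0.163 over the alternatives). DDIT3 (log2 fold change 1.69 ± 0.054), a stress transcription factor, rose. Among 15 mesenchymal genes, 9 rose and 6 were not called, with 9 called adjusted over the list alone (median log2 fold change 1.11, 0.14 on unfiltered TPM, camera adjusted p = 0.00234, adjusted p = 0.102 with an estimated correlation). TGFBI (log2 fold change 2.49 ± 0.068) and SERPINE1 (2.14 ± 0.127), both TGF-beta targets, rose. The list's median was 0.70 without tamoxifen replicate 1. Camera placed the MYC and ribosome biogenesis genes lower than other genes (median log2 fold change -0.24, -0.12 on unfiltered TPM, camera adjusted p = 0.00187, adjusted p = 0.0696 with an estimated correlation), and of 28 members 3 rose, 17 fell and 8 were not called, with 21 called adjusted over the list alone. FBL (log2 fold change -0.70 ± 0.043), a nucleolar methyltransferase, and CDK4 (-0.53 ± 0.041) fell. Of the 22 oxidative phosphorylation nuclear genes, 1 rose, 17 fell and 4 were not called (median log2 fold change -0.31, camera adjusted p = 1.36e-05, adjusted p = 0.0696 with an estimated correlation), and 19 were called adjusted over the list alone. COX6C (log2 fold change -1.45 ± 0.042) and ATP5G1 (-0.79 ± 0.056), subunits of respiratory complexes, fell. Mitochondrially encoded genes were lower on balance (median log2 fold change -0.32, camera adjusted p = 0.000258, adjusted p = 0.287 with an estimated correlation): of 13 members, 10 fell and 3 were not called, with 10 called adjusted over the list alone. MT-CO2 (log2 fold change -0.73 ± 0.044) and MT-CO3 (-0.67 ± 0.039), subunits of cytochrome oxidase, fell, and the mitochondrial share of counts was 4.35 ± 0.0429% against 5.49 ± 0.0628% with DMSO.

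The remaining 11 lists were not called on balance. Their camera adjusted p and median log2 fold change were 0.339 and 0.14 for CDK inhibitors and pocket proteins, 0.0514 and -0.15 for fatty acid synthesis genes, 0.0569 and 0.19 for unfolded protein response genes, 0.198 and 0.03 for aryl hydrocarbon receptor target genes, 0.108 and 0.32 for p53 target genes, 0.479 and 0.03 for receptor tyrosine kinase signalling genes. For the rest they were 0.382 and 0.15 for nuclear receptors and coregulators, 0.416 and -0.05 for luminal epithelial genes, 0.401 and 0.22 for fibroblast markers, 0.0548 and 1.29 for leukocyte markers, 0.172 and 0.38 for endothelial markers. Of these, unfolded protein response genes were called in 4 of 13 alternatives, fatty acid synthesis genes in 3 and aryl hydrocarbon receptor and p53 target genes in 1 each; of 6 fits without 1 library, leukocyte markers were called in 3, fatty acid synthesis genes in 2 and unfolded protein response genes in 1. The mean over the receptor tyrosine kinase list was -0.03 and thus of the other sign than its median. Tamoxifen replicate 1 shared lane 7 with the DMSO libraries, and with it as the lone tamoxifen library, assumed to vary like those of the other groups, 9496 genes were called and the estrogen-induced list had a median log2 fold change of -0.73 (camera adjusted p = 7.23e-07, range 2.65e-09 to 0.0301 over the alternatives); with lane as a term, 9391 genes were called. All p-values measure the spread between libraries only.

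**Figure D1:**
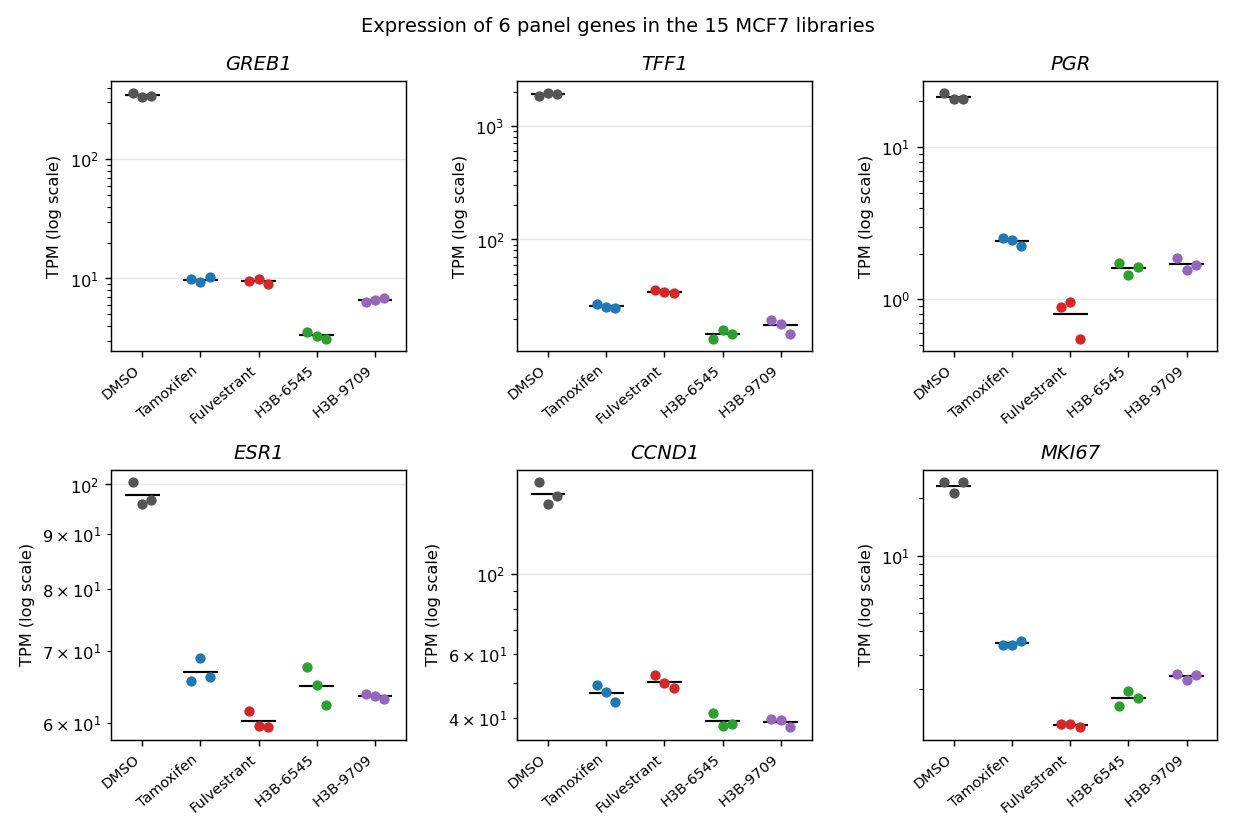
TPM of 6 genes (log axis) in each library of the 5 groups, with a horizontal line at the group mean. GREB1 stood at 345 ± 11.6 TPM with DMSO and at 3.33 ± 0.233 TPM with H3B-6545.

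Fulvestrant, an estrogen receptor antagonist that lowers the receptor protein, was compared with DMSO to show what it changed in the same cells. All 35 measured interferon-stimulated genes rose, and 40 of 44 estrogen-induced genes fell. OAS1, which senses double-stranded RNA, rose from 1.36 ± 0.707 to 90.9 ± 17.0 TPM, a log2 fold change of 5.90 ± 0.270, and IFIT1, which binds viral RNA, reached 142 ± 24.8 TPM from 2.17 ± 0.520, a log2 fold change of 5.52 ± 0.200. SLC6A14, an amino acid transporter, fell from 90.6 ± 3.76 to 0.690 ± 0.0976 TPM, a log2 fold change of -7.21 ± 0.080. In the panel, TFF1 (log2 fold change -5.94 ± 0.065), GREB1 (-5.35 ± 0.054), PGR (-4.97 ± 0.064), PDZK1 (-3.53 ± 0.087), CXCL12 (-3.27 ± 0.076), CCND1 (-1.82 ± 0.042), CCNE2 (-1.68 ± 0.10005), MKI67 (-4.35 ± 0.062) and ESR1 (-0.86 ± 0.035) fell, while ERBB2 (0.94 ± 0.052), HMGCS1 (0.64 ± 0.060) and MYC (0.42 ± 0.041) rose, each at an edgeR adjusted p of 4.21e-10 or less.

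Further low genes were ELOVL2 (log2 fold change -6.51 ± 0.065), SULF1 (-6.26 ± 0.061), an extracellular sulfatase, ADRA2A (-5.93 ± 0.139), an adrenergic receptor, and AGR3 (-5.91 ± 0.185). Further high genes were KLHDC7B (log2 fold change 5.95 ± 0.152), LCN2 (5.81 ± 0.180), an iron-sequestering lipocalin, ADCY5 (5.50 ± 0.106) and DDX60 (5.47 ± 0.269), a helicase of the antiviral response. For these and the 3 genes opening the comparison, the edgeR adjusted p was at most 6.39e-09. The count of called genes was 13597, with 6608 higher and 6989 lower, and 1875 rose and 1837 fell at least 2-fold. The higher share of the calls was 48.6%, and 63.2% on log2(TPM + 1), a scale on which the median log2 fold change of all genes moved from -0.05 to 0.10.

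Of the 29 lists, camera called 19, 13 higher and 6 lower, and 7 of these calls held with an estimated correlation. Among 35 interferon-stimulated genes, all 35 rose, with 35 called adjusted over the list alone (median log2 fold change 3.27, camera adjusted p = 7.63e-19, adjusted p = 0.0762 with an estimated correlation). IFIT5 (log2 fold change 2.76 ± 0.075) and ISG20 (3.14 ± 0.092) had the lowest p-values. Camera placed the MHC class I and antigen processing genes higher than other genes (median log2 fold change 1.63, camera adjusted p = 9.48e-08, adjusted p = 0.0762 with an estimated correlation), and of 14 members all 14 rose, with 14 called adjusted over the list alone. TAP1 (log2 fold change 3.15 ± 0.078) and ERAP1 (1.71 ± 0.060) rose. Of the 40 mitosis and G2/M genes, all 40 fell (median log2 fold change -3.55, camera adjusted p = 8.35e-26), and 40 were called adjusted over the list alone. MKI67 (log2 fold change -4.35 ± 0.062) and PRC1 (-3.34 ± 0.048) had the lowest p-values. Replication and G1/S genes were lower on balance (median log2 fold change -2.08, camera adjusted p = 1.25e-20): of 42 members, 1 rose, 40 fell and 1 was not called, with 42 called adjusted over the list alone. RRM2 (log2 fold change -3.96 ± 0.069) and UHRF1 (-3.70 ± 0.075) fell. Among 44 estrogen-induced genes, 2 rose, 40 fell and 2 were not called, with 42 called adjusted over the list alone (median log2 fold change -1.62, camera adjusted p = 3.13e-18). ELOVL2 (log2 fold change -6.51 ± 0.065) and GFRA1 (-5.08 ± 0.042), a receptor for glial growth factors, fell. Camera placed the estrogen-repressed genes higher than other genes (median log2 fold change 1.06, camera adjusted p = 1.02e-07), and of 26 members 21 rose, 4 fell and 1 was not called, with 25 called adjusted over the list alone. BCAS1 (log2 fold change 3.49 ± 0.043) and EPAS1 (3.53 ± 0.070), a hypoxia-inducible transcription factor, rose.

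Of the 16 NF-kB target genes, 15 rose and 1 fell (median log2 fold change 2.70, 1.11 on unfiltered TPM, camera adjusted p = 6.25e-08), and 16 were called adjusted over the list alone. TNFAIP3 (log2 fold change 4.05 ± 0.102), a deubiquitinase that dampens NF-kB, and NFKBIA (1.94 ± 0.041) rose. NRF2 target genes were higher on balance (median log2 fold change 1.32, camera adjusted p = 4.31e-08): of 24 members, 20 rose, 3 fell and 1 was not called, with 23 called adjusted over the list alone. AKR1C2 (log2 fold change 3.55 ± 0.069) and NQO1 (1.78 ± 0.037), a quinone reductase, rose. Among 27 lysosome and autophagy genes, 23 rose, 3 fell and 1 was not called, with 26 called adjusted over the list alone (median log2 fold change 0.61, camera adjusted p = 1.02e-07). SQSTM1 (log2 fold change 2.17 ± 0.040) and PSAP (1.28 ± 0.039) rose. Camera placed the aryl hydrocarbon receptor target genes higher than other genes (median log2 fold change 0.53, 1.11 with a mean CPM of at least 5, camera adjusted p = 0.00353, adjusted p = 0.0604 with an estimated correlation), and of 8 members 5 rose and 3 were not called, with 5 called adjusted over the list alone. CYP1A1 (log2 fold change 5.10 ± 0.098), a cytochrome of xenobiotic metabolism, rose.

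Of the 19 basal epithelial genes, 15 rose and 4 fell (median log2 fold change 1.64, 0.69 on unfiltered TPM, camera adjusted p = 0.00142, adjusted p = 0.0573 with an estimated correlation), and 19 were called adjusted over the list alone. That call was lost with a mean CPM of at least 5 (camera adjusted p from 0.000103 to 0.156 over the alternatives). KRT81 (log2 fold change 5.41 ± 0.090) rose and CAV1 (-3.01 ± 0.066), the caveolae protein, fell. Hypoxia and glycolysis genes were lower on balance (median log2 fold change -0.82, camera adjusted p = 0.000741, adjusted p = 0.0604 with an estimated correlation): of 20 members, 5 rose and 15 fell, with 20 called adjusted over the list alone. LDHA (log2 fold change -2.23 ± 0.042) and BNIP3 (-2.22 ± 0.045) fell. Among 22 oxidative phosphorylation nuclear genes, 20 fell and 2 were not called, with 20 called adjusted over the list alone (median log2 fold change -0.35, -0.15 on unfiltered TPM, camera adjusted p = 7.28e-06, adjusted p = 0.0604 with an estimated correlation). COX6C (log2 fold change -1.52 ± 0.042) and ATP5O (-0.68 ± 0.047) fell. Camera placed the mitochondrially encoded genes lower than other genes (median log2 fold change -0.29, -0.12 on unfiltered TPM, camera adjusted p = 0.00403, adjusted p = 0.387 with an estimated correlation), and of 13 members 10 fell and 3 were not called, with 10 called adjusted over the list alone. MT-CO2 (log2 fold change -0.79 ± 0.044) and MT-CO3 (-0.63 ± 0.039) fell, with the mitochondrial share of counts at 4.39 ± 0.182% against 5.49 ± 0.0628% with DMSO. With lane as a term in the fit, 9135 genes were called and the estrogen-induced list had a median of -1.75; no lane held both fulvestrant and DMSO libraries.

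**Figure D2:**
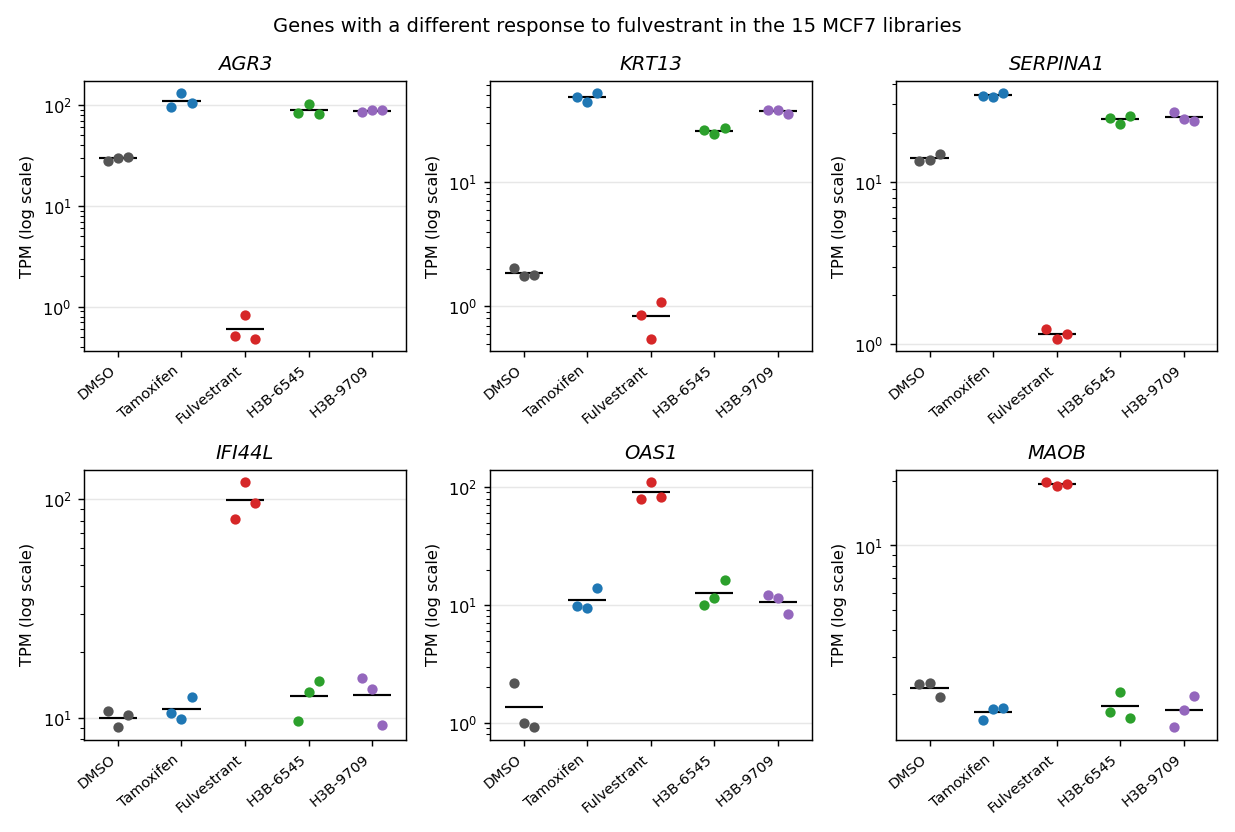
TPM of 6 genes (log axis) per library for the 5 groups, with the group mean as a horizontal line. The interferon-stimulated genes shown reached their highest mean with fulvestrant, OAS1 at 90.9 ± 17.0 and IFI44L at 99.2 ± 19.5 TPM.

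H3B-6545 was compared with DMSO to show which RNA levels it changed. TFF1 fell from 1891 ± 57.3 to 14.7 ± 1.23 TPM, a log2 fold change of -7.08 ± 0.071, and GREB1 from 345 ± 11.6 to 3.33 ± 0.233 TPM, a log2 fold change of -6.89 ± 0.059. PGR (log2 fold change -3.75 ± 0.056), PDZK1 (-1.68 ± 0.071), CXCL12 (-4.20 ± 0.082), CCND1 (-2.13 ± 0.043), CCNE2 (-1.74 ± 0.098), MKI67 (-3.80 ± 0.058) and ESR1 (-0.68 ± 0.035) fell as well, while ERBB2 (0.69 ± 0.052) and MYC (0.33 ± 0.041) rose, all at an edgeR adjusted p of 7.11e-08 or less. HMGCS1 had a log2 fold change of 0.11 ± 0.061 and was not called (edgeR adjusted p = 0.114), though it was called higher without H3B-6545 replicate 1.

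The low end also held TFF3 (log2 fold change -5.99 ± 0.110), NPY1R (-4.77 ± 0.063), CASP14 (-4.47 ± 0.111) and ELOVL2 (-4.46 ± 0.054). The high end held ACHE (log2 fold change 5.08 ± 0.095), ADCY5 (4.92 ± 0.108), LCN2 (4.75 ± 0.193), HMOX1 (4.54 ± 0.092), which breaks down heme, NT5E (4.50 ± 0.098) and MPPED1 (4.46 ± 0.121). The edgeR adjusted p of these 10 genes was at most 2.29e-15. In all, 12627 genes were called, 6214 higher and 6413 lower, of which 1770 and 1286 changed at least 2-fold.

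Camera called 21 of the 29 lists, 13 higher and 8 lower, and 10 held with an estimated correlation. Of the 40 mitosis and G2/M genes, all 40 fell (median log2 fold change -3.28, camera adjusted p = 1.42e-29), and 40 were called adjusted over the list alone. MKI67 (log2 fold change -3.80 ± 0.058) and PRC1 (-3.17 ± 0.046) fell. Replication and G1/S genes were lower on balance (median log2 fold change -1.95, camera adjusted p = 9.75e-25): of 42 members, 40 fell and 2 were not called, with 40 called adjusted over the list alone. RRM2 (log2 fold change -3.63 ± 0.065) and UHRF1 (-3.39 ± 0.071) fell. Among 44 estrogen-induced genes, 8 rose, 32 fell and 4 were not called, with 40 called adjusted over the list alone (median log2 fold change -0.88, camera adjusted p = 3.12e-08). GREB1 (log2 fold change -6.89 ± 0.059) and TFF1 (-7.08 ± 0.071) had the lowest p-values. Camera placed the estrogen-repressed genes higher than other genes (median log2 fold change 0.78, camera adjusted p = 4.65e-07), and of 26 members 21 rose, 4 fell and 1 was not called, with 25 called adjusted over the list alone. BCAS1 (log2 fold change 2.76 ± 0.042) and EPAS1 (3.08 ± 0.070) rose. Of the 16 NF-kB target genes, 14 rose and 2 were not called (median log2 fold change 1.502, 0.42 on unfiltered TPM, camera adjusted p = 7.52e-07), and 14 were called adjusted over the list alone. RELB (log2 fold change 2.69 ± 0.116) and NFKBIA (1.12 ± 0.040) rose. NRF2 target genes were higher on balance (median log2 fold change 0.69, camera adjusted p = 7.1e-07): of 24 members, 19 rose, 3 fell and 2 were not called, with 22 called adjusted over the list alone. AKR1C2 (log2 fold change 3.21 ± 0.069) and SLC7A11 (3.53 ± 0.068) rose. Among 35 interferon-stimulated genes, 26 rose, 1 fell and 8 were not called, with 27 called adjusted over the list alone (median log2 fold change 1.33, 0.84 on unfiltered TPM, camera adjusted p = 9.9e-08, adjusted p = 0.263 with an estimated correlation). ISG20 (log2 fold change 2.04 ± 0.096) and OASL (2.15 ± 0.130), an antiviral protein, rose. Camera placed the cholesterol synthesis genes lower than other genes (median log2 fold change -0.30, -0.16 on unfiltered TPM, camera adjusted p = 0.0004), and of 25 members 2 rose, 18 fell and 5 were not called, with 20 called adjusted over the list alone. FDFT1 (log2 fold change -1.16 ± 0.047) and EBP (-1.13 ± 0.062), a sterol isomerase, fell. Of the 13 mitochondrially encoded genes, 12 fell and 1 was not called (median log2 fold change -0.35, camera adjusted p = 0.000433, adjusted p = 0.266 with an estimated correlation), and 12 were called adjusted over the list alone. MT-CO2 (log2 fold change -0.81 ± 0.044) and MT-CO3 (-0.72 ± 0.039) fell, and the mitochondrial share of counts was 4.23 ± 0.178% against 5.49 ± 0.0628% with DMSO. All H3B-6545 libraries ran in lane 3, where no library of the DMSO, tamoxifen or fulvestrant groups ran, so lane and group cannot be told apart here. Where a lane term could be fitted beside group, edgeR called 0 genes for lane 6 and 2 for lane 4 against lane 7 and 0 for lane 2 against lane 3, with 638, 1204 and 484 of 21875 at an unadjusted p below 0.05; lane 3 against lane 7 has no such estimate.

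H3B-9709 was compared with DMSO in the same way. TFF1 fell from 1891 ± 57.3 to 17.5 ± 2.51 TPM, a log2 fold change of -6.83 ± 0.069, and GREB1 from 345 ± 11.6 to 6.61 ± 0.202 TPM, a log2 fold change of -5.81 ± 0.055. In the panel, PGR (log2 fold change -3.63 ± 0.056), PDZK1 (-1.73 ± 0.071), CXCL12 (-4.01 ± 0.080), CCND1 (-2.17 ± 0.043), CCNE2 (-1.67 ± 0.097), MKI67 (-3.42 ± 0.056) and ESR1 (-0.70 ± 0.035) fell, and ERBB2 (0.56 ± 0.052), MYC (0.23 ± 0.041) and HMGCS1 (0.22 ± 0.060) rose, each at an edgeR adjusted p of 0.00292 or less. TFF3 (log2 fold change -6.08 ± 0.111), CASP14 (-4.65 ± 0.112), NPY1R (-4.35 ± 0.060) and ELOVL2 (-4.26 ± 0.053) stood next to TFF1 and GREB1 at the low end, and ACHE (4.85 ± 0.096), ADCY5 (4.69 ± 0.109), NT5E (4.60 ± 0.097), LCN2 (4.47 ± 0.198), TGFB2 (4.36 ± 0.073) and HMOX1 (4.32 ± 0.092) at the high end, at an edgeR adjusted p of 1.19e-14 or less. Of the genes tested, 12366 were called, 6093 higher and 6273 lower, with 1642 up and 1242 down at least 2-fold.

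For H3B-9709, camera called 21 of the 29 lists, 12 higher and 9 lower, and 10 held with an estimated correlation. Mitosis and G2/M genes were lower on balance (median log2 fold change -2.98, camera adjusted p = 8.38e-30): of 40 members, all 40 fell, with 40 called adjusted over the list alone. MKI67 (log2 fold change -3.42 ± 0.056) and PRC1 (-2.93 ± 0.045) fell. Among 42 replication and G1/S genes, 1 rose, 40 fell and 1 was not called, with 41 called adjusted over the list alone (median log2 fold change -1.86, camera adjusted p = 4.79e-25). RRM2 (log2 fold change -3.24 ± 0.063) and UHRF1 (-3.07 ± 0.069) fell. Camera placed the estrogen-induced genes lower than other genes (median log2 fold change -0.84, camera adjusted p = 8.57e-09), and of 44 members 9 rose, 34 fell and 1 was not called, with 43 called adjusted over the list alone. TFF1 (log2 fold change -6.83 ± 0.069) and GREB1 (-5.81 ± 0.055) had the lowest p-values. Of the 26 estrogen-repressed genes, 21 rose, 4 fell and 1 was not called (median log2 fold change 0.76, camera adjusted p = 2.94e-07), and 26 were called adjusted over the list alone. TGFB2 (log2 fold change 4.36 ± 0.073) and BCAS1 (2.62 ± 0.042) rose. NRF2 target genes were higher on balance (median log2 fold change 0.76, camera adjusted p = 8.96e-07): of 24 members, 20 rose, 3 fell and 1 was not called, with 23 called adjusted over the list alone. AKR1C2 (log2 fold change 3.28 ± 0.069) rose. Among 16 NF-kB target genes, 13 rose and 3 were not called, with 13 called adjusted over the list alone (median log2 fold change 1.249, 0.42 on unfiltered TPM, camera adjusted p = 4.57e-06). TNFAIP3 (log2 fold change 2.43 ± 0.112) and NFKBIA (1.00 ± 0.040) rose. Camera placed the interferon-stimulated genes higher than other genes (median log2 fold change 1.16, camera adjusted p = 2.08e-07, adjusted p = 0.251 with an estimated correlation), and of 35 members 25 rose, 1 fell and 9 were not called, with 26 called adjusted over the list alone. ISG20 (log2 fold change 1.80 ± 0.097) and OASL (1.95 ± 0.132) rose. Of the 13 mitochondrially encoded genes, 12 fell and 1 was not called (median log2 fold change -0.38, camera adjusted p = 7.25e-05, adjusted p = 0.24 with an estimated correlation), and 12 were called adjusted over the list alone. MT-CO2 (log2 fold change -0.84 ± 0.044) and MT-CO3 (-0.71 ± 0.039) fell, beside a mitochondrial share of counts of 4.19 ± 0.0505%. Leukocyte markers were called higher with H3B-6545 and H3B-9709 (median log2 fold change 1.54 and 1.56, camera adjusted p = 0.0244 and 0.0265), but had medians of 0.035 and 0.074 on unfiltered TPM, and both calls were lost there and with an estimated correlation. No lane held both H3B-9709 and DMSO libraries, so lane and group cannot be told apart.

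**Figure D3:**
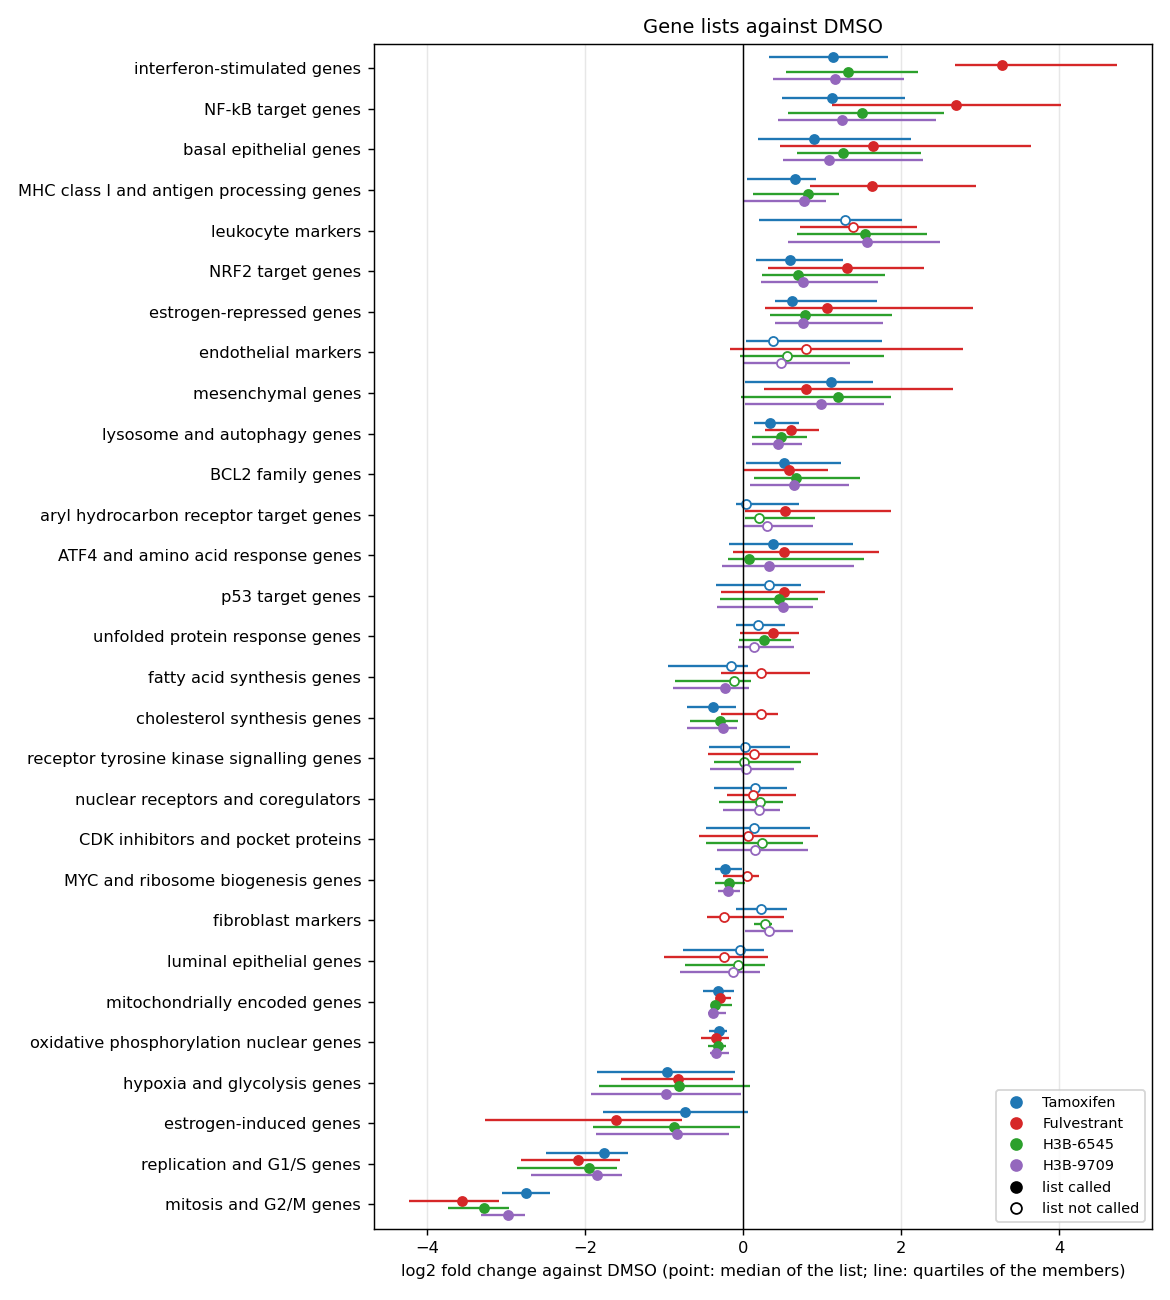
Median log2 fold change (point, filled where camera called the list) and quartiles (line) of the 29 gene lists for each compound against DMSO. The mitosis list had the lowest median with every compound, from -3.55 with fulvestrant to -2.75 with tamoxifen.

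Across the 21875 genes, which are not independent replicates, the log2 fold changes against DMSO had the highest correlation for the 2 H3B compounds, r = 0.944; their covariance of 0.726 was below those of fulvestrant with H3B-6545 (0.772) and H3B-9709 (0.738). The values for tamoxifen were r = 0.918 with H3B-6545, 0.909 with H3B-9709 and 0.781 with fulvestrant, and for fulvestrant 0.835 with H3B-6545 and 0.829 with H3B-9709. Unchanged groups simulated with shared controls gave r = 0.447 to 0.492 and a covariance of 0.0316 to 0.0334, against observed covariances of 0.651 to 0.772. H3B-6545 and H3B-9709 shared 5490 higher and 5620 lower calls, where independent lists of these sizes would share 1731 and 1839. Tamoxifen and fulvestrant shared 4629 higher and 4704 lower calls (1759 and 1911 for independent lists) and moved 550 genes in opposite directions. Unchanged groups shared 0 to 0.05 higher and 0 lower calls on average, but hold no effects. By simulation, shared controls gave little of the covariance, but may add shared calls. IL6, a cytokine gene of the NF-kB list, had 0 counts in every DMSO library. Against a floor of 3 counts over the DMSO group it was 8.30-fold higher with tamoxifen, 51.6-fold with fulvestrant, 15.5-fold with H3B-6545 and 9.85-fold with H3B-9709. The counts with the compounds, 16, 110, 39 and 25 over the groups, were taken as observed. The folds thus allow for error on the DMSO side only. With IL6 at these folds the list medians were 1.13, 2.70, 1.502 and 1.249. IL6 was chosen after its values were seen.

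H3B-6545 and H3B-9709, given at the same dose and time, were compared to show where the 2 compounds differed. GREB1 was lower with H3B-6545, at 3.33 ± 0.233 TPM against 6.61 ± 0.202 with H3B-9709, a log2 fold change of -1.07 ± 0.057. MKI67 was lower too, at 1.79 ± 0.162 against 2.33 ± 0.0871 TPM, a log2 fold change of -0.38 ± 0.062. IGFBP4 (log2 fold change -0.80 ± 0.048), which binds insulin-like growth factors, and DEPDC1 (-0.71 ± 0.129) were lower as well, and MPPED1 (1.13 ± 0.086), SUSD2 (0.45 ± 0.091), a membrane protein, and TRGC1 (0.46 ± 0.108), a T cell receptor constant gene with a close copy that leaves its count uncertain, were higher. For GREB1, MKI67, IGFBP4, DEPDC1, MPPED1, SUSD2 and TRGC1 the edgeR adjusted p was at most 0.0491.

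No other panel gene was called. The confidence interval of the log2 fold change, at a level of 95%, was -0.05 to 0.09 for ESR1, -0.24 to 0.02 for PGR, -0.44 to -0.05 for TFF1, -0.12 to 0.20 for PDZK1 and -0.41 to 0.04 for CXCL12. It was 0.01 to 0.18 for MYC, -0.04 to 0.13 for CCND1, -0.30 to 0.16 for CCNE2, 0.02 to 0.23 for ERBB2 and -0.23 to 0.02 for HMGCS1. Without H3B-6545 replicate 2, MYC and ERBB2 were called higher with H3B-6545. Over the 21875 genes, 18586 (85.0%) had an interval inside a log2 fold change of -1 to 1, and 13912 (63.6%) one inside -0.5 to 0.5.

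edgeR called 94 genes, 51 higher and 43 lower with H3B-6545, and 5 of them differed at least 2-fold: GREB1, MPPED1 (log2 fold change 1.13 ± 0.086) and 3 with clone names, of which CTD-2639E6.4 (-1.45 ± 0.328) and RP11-14O19.2 (-2.22 ± 0.514), chosen after their values were seen, were lower and the third higher. Between the H3B compounds, camera called 6 of the 29 lists, 3 higher and 3 lower, and 2 held with an estimated correlation. Mitosis and G2/M genes were lower on balance (median log2 fold change -0.26, camera adjusted p = 2.22e-25): of 40 members, 10 were lower and 30 were not called, with 24 called adjusted over the list alone. ANLN (log2 fold change -0.57 ± 0.081), an actin-binding protein of cell division, TOP2A (-0.60 ± 0.094), a DNA topoisomerase, and CDK1 (-0.46 ± 0.104) were called lower. Among 42 replication and G1/S genes, 1 was lower and 41 were not called, with 11 called adjusted over the list alone (median log2 fold change -0.14, camera adjusted p = 1.92e-09). The called member was RRM2 (log2 fold change -0.39 ± 0.075). Camera placed the estrogen-induced genes lower than other genes (median log2 fold change -0.03, -0.051 with a lane term, camera adjusted p = 0.00619, adjusted p = 0.294 with an estimated correlation), and of 44 members 4 were lower and 40 were not called, with 10 called adjusted over the list alone. That call was lost without H3B-6545 replicate 2 (camera adjusted p from 0.0022 to 0.294 over the alternatives). The called members were GREB1 (log2 fold change -1.07 ± 0.057), IGFBP4 (-0.80 ± 0.048), KRT13 (-0.51 ± 0.065) and RAPGEFL1 (-0.31 ± 0.047). Of the 16 NF-kB target genes, 1 was higher and 15 were not called (median log2 fold change 0.14, 0.069 on unfiltered TPM, camera adjusted p = 0.000447, adjusted p = 0.184 with an estimated correlation), and 5 were called adjusted over the list alone. The called member was BCL3 (log2 fold change 0.33 ± 0.061), a coactivator of NF-kB. The ATF4 and amino acid response genes were higher on balance (median log2 fold change 0.08, camera adjusted p = 0.000147, adjusted p = 0.0769 with an estimated correlation), with 0 of 21 members called by edgeR over all genes, 7 at an unadjusted p below 0.05, 3 called by DESeq2, 0 by limma on log2(TPM + 1) and 7 called adjusted over the list alone. Its 7 members called over the list alone included SLC7A5 (log2 fold change 0.23 ± 0.055), an amino acid transporter, and TRIB3 (0.17 ± 0.043), a pseudokinase. The interferon-stimulated genes were higher on balance (median log2 fold change 0.13, 0.027 with a lane term, camera adjusted p = 0.0305, adjusted p = 0.741 with an estimated correlation), with 0 of 35 members called by edgeR over all genes, 1 at an unadjusted p below 0.05, 0 called by DESeq2, 0 by limma on log2(TPM + 1) and 0 called adjusted over the list alone. That call was lost with limma on TPM, limma on unfiltered TPM and a lane term and without H3B-6545 replicate 2, H3B-6545 replicate 3 and H3B-9709 replicate 3 (camera adjusted p from 0.0131 to 0.954 over the alternatives). Over fits without 1 library its median ran from 0.03 to 0.21.

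On log2(TPM + 1) the calls of ANLN, MKI67, DEPDC1, SUSD2, TRGC1, RRM2 and BCL3 were lost, and those of DEPDC1, SUSD2, TRGC1, RRM2 and BCL3 also with lane as a term. The calls of SUSD2 and TRGC1 were lost without any of the 6 libraries but H3B-6545 replicate 2. The call of BCL3 was lost without H3B-6545 replicate 1 or 3 or H3B-9709 replicate 2 or 3, that of RRM2 without H3B-6545 replicate 1 or H3B-9709 replicate 2 or 3, and that of DEPDC1 without H3B-6545 replicate 1 or 3 or H3B-9709 replicate 1. The count of 94 called genes depended on single libraries: it was 32, 1030 and 41 without H3B-6545 replicate 1, 2 or 3, and 40, 29 and 27 without H3B-9709 replicate 1, 2 or 3, the last being the only library of the pair outside lane 3. With lane as a term the count was 25 and the estrogen-induced list had a median of -0.05; the share of higher calls, 54.3%, was 33.3% on log2(TPM + 1), 43.5% with library size alone and 70.4% with DESeq2.

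**Figure D4:**
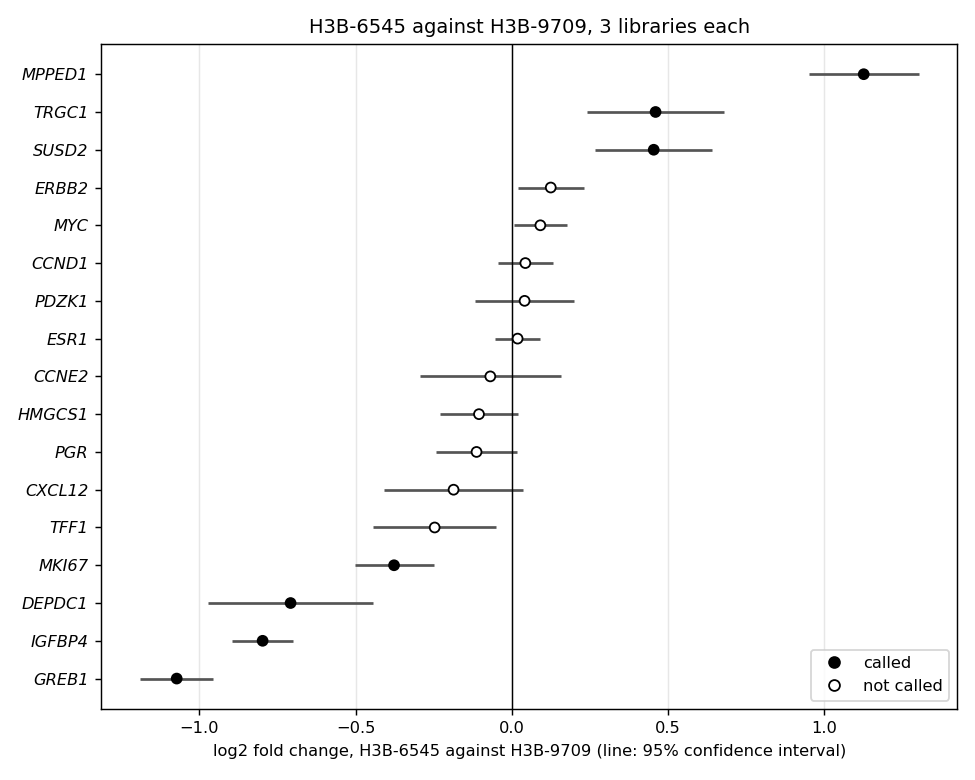
Log2 fold change of H3B-6545 against H3B-9709 with its confidence interval (95%) for panel genes and the genes with the largest differences, filled where called. GREB1 lay at -1.07 and MPPED1 at 1.13.

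Fulvestrant and tamoxifen, the pair of established drugs, were compared directly. Interferon genes were higher with fulvestrant: HERC6, a ligase of the interferon response, stood at 18.9 ± 2.98 TPM against 1.70 ± 0.0121 with tamoxifen, a log2 fold change of 3.50 ± 0.146. AGR3 was nearly absent with fulvestrant, at 0.609 ± 0.189 TPM against 110.2 ± 18.2, a log2 fold change of -7.85 ± 0.152. Other high genes were MAOB (log2 fold change 3.49 ± 0.101), a monoamine oxidase, and IFI44L (3.28 ± 0.193), and other low genes were MPPED1 (-7.61 ± 0.176) and IGHG4 (-7.46 ± 0.229). In the panel, PGR (log2 fold change -1.63 ± 0.074), PDZK1 (-2.04 ± 0.097), MKI67 (-1.48 ± 0.066) and ESR1 (-0.21 ± 0.035) were lower with fulvestrant, and TFF1 (0.36 ± 0.084), CXCL12 (0.51 ± 0.102), ERBB2 (0.28 ± 0.052), HMGCS1 (0.62 ± 0.062) and MYC (0.12 ± 0.041) were higher. The edgeR adjusted p of all these genes was at most 0.0163, with the call of MYC lost with a mean CPM of at least 5, with lane as a term, within lane 6 and without fulvestrant replicate 2. The log2 fold changes of GREB1 (-0.12 ± 0.051), CCND1 (0.08 ± 0.042) and CCNE2 (-0.04 ± 0.117) did not pass the test (edgeR adjusted p = 0.0561, 0.145 and 0.821), though GREB1 was called lower with library size alone, with either other filter on low counts, without tamoxifen replicate 2 and without fulvestrant replicate 1.

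Between fulvestrant and tamoxifen, camera called 18 of the 29 lists, 15 higher and 3 lower, and 15 held with an estimated correlation. Camera placed the interferon-stimulated genes higher than other genes (median log2 fold change 2.37, camera adjusted p = 2.77e-26), and of 35 members all 35 were higher, with 35 called adjusted over the list alone. IFIT5 (log2 fold change 2.07 ± 0.074) and ISG20 (1.75 ± 0.085) were higher. Of the 14 MHC class I and antigen processing genes, all 14 were higher (median log2 fold change 1.09, camera adjusted p = 1.65e-10), and 14 were called adjusted over the list alone. TAP1 (log2 fold change 2.10 ± 0.075) and TAPBP (0.95 ± 0.051), which loads peptides, were higher. Cholesterol synthesis genes were higher on balance (median log2 fold change 0.52, camera adjusted p = 4.13e-08): of 25 members, 19 were higher, 2 were lower and 4 were not called, with 21 called adjusted over the list alone. LDLR (log2 fold change 1.34 ± 0.048), the LDL receptor, and CYP51A1 (1.00 ± 0.046), a sterol demethylase, were higher. Among 15 fatty acid synthesis genes, 12 were higher, 1 was lower and 2 were not called, with 14 called adjusted over the list alone (median log2 fold change 0.59, camera adjusted p = 9.35e-07). ACSL3 (log2 fold change 1.36 ± 0.044), an acyl-CoA synthetase, and SCD (0.82 ± 0.045) were higher. Camera placed the NF-kB target genes higher than other genes (median log2 fold change 1.52, 0.75 on unfiltered TPM, camera adjusted p = 6.13e-09), and of 16 members 14 were higher, 1 was lower and 1 was not called, with 16 called adjusted over the list alone. NFKBIA (log2 fold change 1.11 ± 0.040) was higher and IER3 (-1.79 ± 0.046), an early response gene, lower.

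Of the 44 estrogen-induced genes, 9 were higher, 28 were lower and 7 were not called (median log2 fold change -0.58, camera adjusted p = 2.37e-11), and 39 were called adjusted over the list alone. GFRA1 (log2 fold change -4.35 ± 0.041) and SERPINA1 (-5.30 ± 0.090) were lower. Mitosis and G2/M genes were lower on balance (median log2 fold change -0.88, -0.51 on unfiltered TPM, camera adjusted p = 3.37e-14): of 40 members, 1 was higher, 34 were lower and 5 were not called, with 35 called adjusted over the list alone. MKI67 (log2 fold change -1.48 ± 0.066) was lower. Among 42 replication and G1/S genes, 2 were higher, 25 were lower and 15 were not called, with 29 called adjusted over the list alone (median log2 fold change -0.28, -0.18 on unfiltered TPM, camera adjusted p = 4.63e-05). RRM2 (log2 fold change -0.99 ± 0.081) and MCM2 (-0.66 ± 0.055), part of the replicative helicase, were lower. Camera placed the estrogen-repressed genes higher than other genes (median log2 fold change 0.25, camera adjusted p = 0.00132), and of 26 members 16 were higher, 7 were lower and 3 were not called, with 23 called adjusted over the list alone. MAOB (log2 fold change 3.49 ± 0.101) and BCAS1 (1.09 ± 0.039) were higher.

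edgeR called 9094 genes, 4860 higher and 4234 lower with fulvestrant, 588 and 720 of them at least 2-fold. The higher share was 53.4%, and 64.5% on log2(TPM + 1). Within lane 6, which held 2 libraries of each group, 7213 genes were called and the estrogen-induced list had a median of -0.57, and with lane as a term 6978 genes were called.

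H3B-6545 was set against tamoxifen to show where the code-named compound and the older drug differed. GREB1 was lower with H3B-6545, at 3.33 ± 0.233 against 9.79 ± 0.427 TPM, a log2 fold change of -1.66 ± 0.057, and TFF1 was lower at 14.7 ± 1.23 against 25.8 ± 1.03 TPM, a log2 fold change of -0.78 ± 0.094. MKI67 was lower as well, at 1.79 ± 0.162 against 3.46 ± 0.107 TPM, a log2 fold change of -0.94 ± 0.061. Further genes that were lower were SULF1 (log2 fold change -1.27 ± 0.051), IGFBP4 (-1.18 ± 0.048), PGR (-0.40 ± 0.063), CXCL12 (-0.42 ± 0.111) and CCND1 (-0.23 ± 0.043), and genes that were higher were HMOX1 (0.70 ± 0.069), STRA6 (0.70 ± 0.119), a receptor for retinol-binding protein, and TIMP3 (0.78 ± 0.045), an inhibitor of metalloproteinases. The call of CXCL12 was lost with limma on TPM, with only the 6 libraries compared and without replicate 1 or 3 of either group, those of PGR, STRA6 and SLC7A11 with limma on log2(TPM + 0.1) and that of CCND1 with limma on unfiltered TPM. The edgeR adjusted p was at most 0.0268 for these genes. ESR1, PDZK1, MYC, CCNE2, ERBB2 and HMGCS1 were not called, and their intervals were -0.10 to 0.05, -0.36 to -0.04, -0.06 to 0.11, -0.33 to 0.14, -0.08 to 0.14 and -0.04 to 0.22.

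Against tamoxifen, camera called 16 of the 29 lists, 12 higher and 4 lower, and 5 held with an estimated correlation. Of the 40 mitosis and G2/M genes, 28 were lower and 12 were not called (median log2 fold change -0.51, camera adjusted p = 8.24e-43), and 39 were called adjusted over the list alone. MKI67 (log2 fold change -0.94 ± 0.061) and ANLN (-0.84 ± 0.082) were lower. Estrogen-induced genes were lower on balance (median log2 fold change -0.20, camera adjusted p = 3.41e-21): of 44 members, 22 were lower and 22 were not called, with 28 called adjusted over the list alone. GREB1 (log2 fold change -1.66 ± 0.057) and IGFBP4 (-1.18 ± 0.048) were lower. Among 42 replication and G1/S genes, 12 were lower and 30 were not called, with 25 called adjusted over the list alone (median log2 fold change -0.19, camera adjusted p = 1.99e-18). RRM2 (log2 fold change -0.66 ± 0.076) and UHRF1 (-0.58 ± 0.084) were lower. Camera placed the NRF2 target genes higher than other genes (median log2 fold change 0.15, 0.095 on unfiltered TPM, camera adjusted p = 3.03e-10), and of 24 members 8 were higher and 16 were not called, with 13 called adjusted over the list alone. HMOX1 (log2 fold change 0.70 ± 0.069) and TXNRD1 (0.38 ± 0.043) were higher. Of the 21 ATF4 and amino acid response genes, 7 were higher, 1 was lower and 13 were not called (median log2 fold change 0.14, 0.087 on unfiltered TPM, camera adjusted p = 3.24e-08), and 13 were called adjusted over the list alone. SLC7A11 (log2 fold change 0.43 ± 0.055) and DDIT3 (0.34 ± 0.049) were higher. The p53 target genes were higher on balance (median log2 fold change 0.08, camera adjusted p = 8.45e-07, adjusted p = 0.0562 with an estimated correlation): of 23 members, 6 were higher and 17 were not called, with 9 called adjusted over the list alone. CDKN1A (log2 fold change 0.32 ± 0.040) and AEN (0.40 ± 0.044) were higher, and without tamoxifen replicate 3 the list's median was 0.040. Among 35 interferon-stimulated genes, 2 were higher and 33 were not called, with 2 called adjusted over the list alone (median log2 fold change 0.26, 0.17 on unfiltered TPM, camera adjusted p = 8.45e-07, adjusted p = 0.332 with an estimated correlation). ISG20 (log2 fold change 0.64 ± 0.089) and OASL (0.48 ± 0.116) were the called members, OASL not on log2(TPM + 1) nor without tamoxifen replicate 1 or 2 or H3B-6545 replicate 3.

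edgeR called 812 genes, 377 higher and 435 lower with H3B-6545, and 12 and 22 of these at least 2-fold. The count was 474 without H3B-6545 replicate 3 and 502 without tamoxifen replicate 3, and the higher share moved from 46.4% to 30.7% on log2(TPM + 1). No lane held both groups, so lane and group cannot be told apart.

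H3B-6545 was also set against fulvestrant. AGR3 was far higher with H3B-6545, at 89.1 ± 11.2 against 0.609 ± 0.189 TPM, a log2 fold change of 7.64 ± 0.153. IFI44L, an interferon-stimulated gene, was lower, at 12.6 ± 2.59 against 99.2 ± 19.5 TPM, a log2 fold change of -3.04 ± 0.186. MAOB (log2 fold change -3.39 ± 0.096) and HERC6 (-3.03 ± 0.134) were lower too, and MPPED1 (7.09 ± 0.184) and IGHG4 (6.46 ± 0.253) were higher. In the panel, GREB1 (log2 fold change -1.54 ± 0.056), TFF1 (-1.15 ± 0.089), CXCL12 (-0.93 ± 0.102), HMGCS1 (-0.53 ± 0.061), CCND1 (-0.31 ± 0.042) and ERBB2 (-0.25 ± 0.052) were lower with H3B-6545, and PDZK1 (1.84 ± 0.096), PGR (1.23 ± 0.074), MKI67 (0.55 ± 0.068) and ESR1 (0.18 ± 0.035) were higher. The edgeR adjusted p of these genes was at most 0.000265. The log2 fold changes of MYC (-0.09 ± 0.041) and CCNE2 (-0.06 ± 0.113) did not pass the test (edgeR adjusted p = 0.0692 and 0.731), though MYC was called lower with both other normalizations, DESeq2, limma on TPM and without H3B-6545 replicate 1.

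Against fulvestrant, camera called 13 of the 29 lists, 2 higher and 11 lower, and 9 held with an estimated correlation. Camera placed the interferon-stimulated genes lower than other genes (median log2 fold change -2.23, camera adjusted p = 9.53e-28, adjusted p = 0.0508 with an estimated correlation), and of 35 members all 35 were lower, with 35 called adjusted over the list alone. IFIT5 (log2 fold change -1.85 ± 0.071) and OASL (-1.65 ± 0.098) were lower. Of the 14 MHC class I and antigen processing genes, all 14 were lower (median log2 fold change -0.89, camera adjusted p = 4.59e-10, adjusted p = 0.0563 with an estimated correlation), and 14 were called adjusted over the list alone. TAP1 (log2 fold change -1.88 ± 0.072) and TAPBP (-0.92 ± 0.051) were lower. NF-kB target genes were lower on balance (median log2 fold change -1.07, -0.70 on unfiltered TPM, camera adjusted p = 2.96e-08): of 16 members, 1 was higher, 14 were lower and 1 was not called, with 16 called adjusted over the list alone. NFKBIA (log2 fold change -0.82 ± 0.039) was lower and IER3 (1.56 ± 0.046) higher. Among 25 cholesterol synthesis genes, 2 were higher, 19 were lower and 4 were not called, with 22 called adjusted over the list alone (median log2 fold change -0.51, camera adjusted p = 2.76e-08). LDLR (log2 fold change -1.07 ± 0.047) and CYP51A1 (-0.86 ± 0.045) were lower. Camera placed the fatty acid synthesis genes lower than other genes (median log2 fold change -0.48, camera adjusted p = 1.61e-07), and of 15 members 1 was higher, 12 were lower and 2 were not called, with 14 called adjusted over the list alone. ACSL3 (log2 fold change -1.28 ± 0.044) and SREBF1 (-1.09 ± 0.053), a transcription factor of lipid synthesis, were lower.

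Of the 44 estrogen-induced genes, 27 were higher, 11 were lower and 6 were not called (median log2 fold change 0.40, camera adjusted p = 3.24e-08), and 40 were called adjusted over the list alone. GFRA1 (log2 fold change 3.93 ± 0.041) and SERPINA1 (4.80 ± 0.092) were higher. Mitosis and G2/M genes were higher on balance (median log2 fold change 0.32, 0.12 on unfiltered TPM, camera adjusted p = 0.000745, adjusted p = 0.189 with an estimated correlation): of 40 members, 20 were higher, 4 were lower and 16 were not called, with 25 called adjusted over the list alone. MKI67 (log2 fold change 0.55 ± 0.068) and MYBL2 (1.03 ± 0.083), a cell cycle transcription factor, were higher. edgeR called 8363 genes, 3785 higher and 4578 lower with H3B-6545, 585 and 462 of them at least 2-fold. The higher share was 45.3%, and 27.2% on log2(TPM + 1). As no lane held both groups, lane and group cannot be told apart.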

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

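The lane 7 fits of tamoxifen against DMSO, the lane 6 fit of the estrogen-induced list, the alternatives of the other lists and those of the set of 17 genes were tests chosen after the data were seen. Over the alternatives, 226 of 280 counts stayed within 1.5 times and 54 moved beyond it; of the values of named genes 6322 of 6443 kept direction and call, 103 lost the call, 18 gained one and 0 reversed. Of the list values 3853 of 4061 kept direction and call, 124 lost it, 83 gained one and 1 reversed: for basal epithelial genes, fulvestrant against tamoxifen, camera turned from higher to lower with a mean CPM of at least 5, not called, while the median stayed above 0 at 0.18 (camera adjusted p = 0.997, range 0.00207 to 0.997 over the alternatives). Of 132 medians of called lists, 55 moved by over 1.5 times under some setting: 48 on a TPM scale, 17 under other alternatives and 9 without 1 library, some under several. The counts of called genes against DMSO and between fulvestrant and tamoxifen or H3B-6545 stayed within 1.5 times under every alternative tried. Between the H3B compounds, 94 genes became 230 with DESeq2, 186 with no filter on low counts, 42 with only the 6 libraries compared, 25 with lane as a term, 9 on log2(TPM + 1), 7 on log2(TPM + 0.1) and 12 on unfiltered TPM. All 94 were among the 1030 called without H3B-6545 replicate 2. All 27 called without H3B-9709 replicate 3 were among the 94. The estrogen-induced list of that pair had a median of -0.033 with an estimated correlation, where its call was lost (camera adjusted p = 0.294, range 0.0022 to 0.294 over the alternatives), and without single libraries its median ran from -0.057 (without H3B-6545 replicate 2, where its call was lost too, camera adjusted p = 0.141) to -0.029. H3B-6545 against tamoxifen gave 812 genes, but 397 on log2(TPM + 1), 356 on log2(TPM + 0.1), 305 on unfiltered TPM, 474 without H3B-6545 replicate 3, 502 without tamoxifen replicate 3 and 911 without H3B-6545 replicate 2. At 2-fold, counts fell with a mean CPM of at least 5 and on log2(TPM + 1): from 2593 to 942 and 1189 for tamoxifen against DMSO, 3712 to 1385 and 1868 for fulvestrant, 3056 to 1097 and 1350 for H3B-6545, 2884 to 1005 and 1236 for H3B-9709, 1308 to 413 and 539 between fulvestrant and tamoxifen, 1047 to 313 and 388 for H3B-6545 against fulvestrant, and 34 to 7 and 9 against tamoxifen (21 with DESeq2). Unfiltered TPM gave 1181, 1871, 1348, 1232, 532, 382 and 7 in the same order. Between the H3B compounds the 5 genes at 2-fold became 2 with DESeq2 or a mean CPM of at least 5, 1 on log2(TPM + 0.1), 8 with no filter or with only the 6 libraries compared, 19 without H3B-6545 replicate 2 and 3 without H3B-9709 replicate 3, and no gene called by limma on log2(TPM + 1) reached 2-fold. Fits with fewer libraries have fewer degrees of freedom, and a mean CPM of at least 5 left 11542 genes in place of 21875. Other causes were not tested. At the depth of the smallest library, 29.96 megacounts, IL6 and other genes with few counts have bounds or wide intervals rather than firm folds.

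The replicate numbers were checked for pairing: libraries with the same number had a median correlation of deviations of -0.00237 (-0.0499 to 0.0607 over 30 pairs), and 6 of 15 libraries correlated best with their own number. With a replicate block the counts of called genes were 12074, 13757, 12835 and 12577 against DMSO (tamoxifen, fulvestrant, H3B-6545, H3B-9709), 365 between the H3B compounds (10 at 2-fold), 8745 and 1053 for H3B-6545 against fulvestrant and tamoxifen, and 9421 between fulvestrant and tamoxifen. The block also ended the calls of p53 target genes with H3B-6545 (camera adjusted p = 0.0579), ATF4 and amino acid response genes with H3B-9709 (0.0627) and interferon-stimulated genes between the H3B compounds (0.0609). It added those of aryl hydrocarbon receptor target genes with H3B-9709 (0.0480), mesenchymal genes for H3B-6545 against fulvestrant (0.0392), HMGCS1 with H3B-6545 (edgeR adjusted p = 0.0474), MYC for H3B-6545 against fulvestrant (0.0354) and GREB1 for fulvestrant against tamoxifen (0.0367), and changed no other call of a named gene or list.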

Other observations

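The tests within lane 6 and without single libraries for interferon-stimulated genes were chosen after the result was seen, as were the set of 17 genes, its count filter and its overlap with the estrogen-induced list. Receptor tyrosine kinase signalling genes, nuclear receptors and coregulators, and CDK inhibitors and pocket proteins, not called by camera, held members that moved both ways. The fry test called them for tamoxifen against DMSO (adjusted p at most 1.50036e-14). There 11805 of 21875 genes were called, so this sets no list apart. Among receptor tyrosine kinases, EGFR rose with every compound (log2 fold change 0.55 with tamoxifen to 1.58 with fulvestrant), as did ERBB4 (0.94 to 1.17) and FGFR2 (0.88 with H3B-6545 to 1.82 with fulvestrant), while IGF1R fell (-0.83 with tamoxifen to -2.08 with fulvestrant). FGFR4 rose with fulvestrant (log2 fold change 1.56 ± 0.060), fell with tamoxifen (-0.39 ± 0.065) and H3B-9709 (-0.32 ± 0.063) and was not called with H3B-6545. TGFA rose with fulvestrant (log2 fold change 0.50) and fell with tamoxifen (-1.20), H3B-6545 (-1.09) and H3B-9709 (-1.12). Among nuclear receptors, NR3C1 rose with every compound (log2 fold change 1.32 with tamoxifen to 2.57 with fulvestrant), as did PPARG (1.63 with H3B-9709 to 2.52) and the coactivator gene NCOA1 (1.19 to 1.76), while AR fell (-0.49 with fulvestrant to -0.62 with H3B-6545). Of the CDK inhibitors, CDKN1A (log2 fold change 1.495 with tamoxifen to 1.85 with fulvestrant) and CDKN2B (2.13 to 2.96) rose, and CDKN2C (-2.02 to -3.04) and CDKN1B (-0.48 with fulvestrant to -0.65 with H3B-6545) fell. All these calls had an edgeR adjusted p of 0.000920 or less.

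Interferon-stimulated genes were higher with fulvestrant than with tamoxifen in all 35 members (median log2 fold change 2.37). The tables argue against lane as the cause, since within lane 6 the median was 2.48 (camera adjusted p = 1.06e-26, range 1.07e-36 to 0.0427 over the alternatives). They also argue against a single library, since without each of the 6 in turn the median stayed between 2.23 and 2.46. A response of the cells to fulvestrant stays open as a hypothesis and was not tested.

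Mitosis and G2/M genes were lower on balance with H3B-6545 than with H3B-9709, with a median log2 fold change of -0.26 over 40 members, of which 10 were called lower and 30 were not called. The tables argue against lane as the cause, since without H3B-9709 replicate 3, the library outside lane 3, the median was -0.28 (camera adjusted p = 3.67e-25). They argue as well against a single library, as the median without each of the 6 lay between -0.28 and -0.24, and against the scaling, as it was -0.28 with library size alone (camera adjusted p = 3.28e-24; range 1.17e-26 to 0.00397 over the alternatives). That H3B-6545 slows division further at 100 nM is a hypothesis that was not tested.

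A set of 17 genes rose at least 2-fold with tamoxifen, H3B-6545 and H3B-9709 and fell at least 2-fold with fulvestrant, among them NKAIN1 (25.8 TPM with DMSO, 74.9 with tamoxifen, 9.54 with fulvestrant) and KIF12 (14.1, 70.4 and 4.73 TPM), both chosen after their values were seen, KRT13, AGR3 and 3 immunoglobulin heavy chain genes with close copies, IGHE, IGHG4 and IGHG2. This was fewer than the 103.7 genes expected of independent lists, and 1 gene, P2RY6, went the opposite way. Within lane 6, all 17, chosen for this gap, were called lower with fulvestrant than tamoxifen, which argues against lane for the gap. For the rise with the H3B compounds, with 0 lanes shared with DMSO, lane and group cannot be told apart. Noise at low counts stays open for part of the set, which held 6 genes on log2(TPM + 1): 11 of the 17 had a mean CPM of at least 5, but the rise itself lifts that mean. A partial agonist response stays open too: 2 members of the estrogen-induced list, KRT13 and AGR3, were in the set, but 40 of the 44 genes of that list fell with fulvestrant, so the selection itself favours its members.

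For each of the 8 comparisons the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave the counts of called genes stated above, from 94 between the H3B compounds to 13597 for fulvestrant against DMSO. The highest of the other splits was 1 gene between fulvestrant and tamoxifen and 0 in the other comparisons. Each of these splits mixes the groups and so adds their difference to the spread. Their low counts give no rate of false calls.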
